A study of Mus musculus with 16 samples.

How the data were processed

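The values are raw gene-level read counts as deposited by the authors, with 1 count per gene and library, and no per-sample column was left unused. Per the submitters' processing notes, reads were checked with FastQC 0.11.5 and aligned to GRCm38 with STAR 2.7.6a. The counting program, its strand setting and the annotation release are not given in the sources used here. Libraries were prepared with TruSeq kits, either the unstranded version or the stranded mRNA version, and the labels do not say which kit was used for which library. Counts of genes that overlap on opposite strands, and of close paralogs such as the H2, Gbp and globin families, are therefore uncertain.

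The table held 52636 genes, of which 99.6% had a symbol, and 147 that shared a symbol were named by identifier. A further 3047 genes of the reference annotation were not analysed here, 2943 of them on chromosomes 14 to 19. Genes were kept by edgeR's filterByExpr over the 6 groups (minimum count 10, minimum total 15), which left 19646. TMM factors ran from 0.916 to 1.07. All 16 libraries entered 1 edgeR quasi-likelihood fit with a mean for each of the 6 groups, so that all groups shared the estimate of spread per gene, and p was adjusted by Benjamini-Hochberg within each comparison at a threshold of 0.05. No replicate block was used, since the labels do not say that a number marks an animal, although all 5 male libraries are number 2 in the descriptions. Correlation between libraries of a group was 0.964 to 0.986, and no pair of libraries was a duplicate.

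The 45 gene lists were tested with limma's camera on voom values of the same genes and design, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 45 lists. The test was repeated with the correlation estimated from the data, and with fry. The 12 to 20 lists that passed per tissue compare with 11, 11 and 23 by fry for liver, lung and heart, where fry asks whether a list moved 1 way on balance and not whether it moved more than other genes. The lists, tests, groups, other settings to be tried and the rule for named genes were fixed before the data were examined.

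Named genes were Erg and Fli1, a panel of 12 endothelial genes (Cdh5, Pecam1, Kdr, Tek, Tie1, Vwf, Nos3, Thbd, Emcn, Cldn5, Vcam1 and Procr), and per tissue the 6 largest rises and 6 largest falls. For these a gene had to pass 0.05, every library of one group had to lie above every library of the other, the higher group had to reach 10 CPM, and predicted genes and members of other-cell lists were left out. For each list described, up to 4 members with the smallest adjusted p could be named, and for differences between tissues 4 genes each way, where full separation and 10 CPM were required in at least 1 of both tissues. Tissue comparisons named up to 4 members of the 3 tissue-specific endothelial lists. Ratios for genes with 1 to 3 counts in a group carry a 95% counting interval. List medians were also computed with genes that had no count in a group at a bound of 3 counts. Genes with 1 to 3 counts kept their fitted value in these medians.

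In a self-test, changes were simulated for 200 genes per tissue in counts shaped like these. Recovery of 2-fold changes was 48%, 60% and 43% in liver, lung and heart and that of 4-fold changes 88%, 91% and 82%, and 4.23%, 1.95% and 4.58% of calls were false. Simulated genes were drawn independently, and far fewer were changed than were called in the real data. These rates therefore need not hold for the real calls. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.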

Results

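Gene-level read counts from 16 poly(A) RNA sequencing libraries of mouse endothelial cells were analysed. The cells came from liver, lung and heart of animals labelled wild type or Erg and Fli1 double knockout, at day 10 after tamoxifen. Erg and Fli1 encode transcription factors of the ETS family that are active in endothelial cells. Endothelial cells had been marked in the living animal with an injected antibody against VE-cadherin and released with collagenase and dispase. They had then been sorted as live CD45-negative cells positive for CD31 and VE-cadherin. Liver and lung had 3 control and 3 knockout-labelled libraries each, and heart had 2 of each. Some replicates may be technical, since nothing in the labels says that all came from separate animals, though groups with male and female libraries hold more than 1 animal. Total counts per library ran from 30226340 to 41449054. Levels are CPM (counts scaled to the effective library size) as mean ± SD over libraries, with n = 3 per group in liver and lung and n = 2 in heart. The words "rose" and "fell" compare knockout-labelled with control libraries by edgeR quasi-likelihood tests with Benjamini-Hochberg adjusted p. The log2 fold changes are followed by their standard error (SE) where one is given. Counting intervals and floors cover counting error only.

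On the first 2 principal components, with 49.6% and 22.2% of the variance, the libraries grouped by tissue. The third, with 8.14%, separated every control from every knockout-labelled library. By Xist and Y-linked genes, 1 of the 3 libraries in each liver and lung group was male, as was 1 of the 2 knockout-labelled heart libraries, and both heart controls were female. Every male library was number 2 of its group in the descriptions, where the heart control titled 2 is number 3. Mitochondrial genes took 0.957% to 2.85% of the counts of a library.

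**Figure D1:**
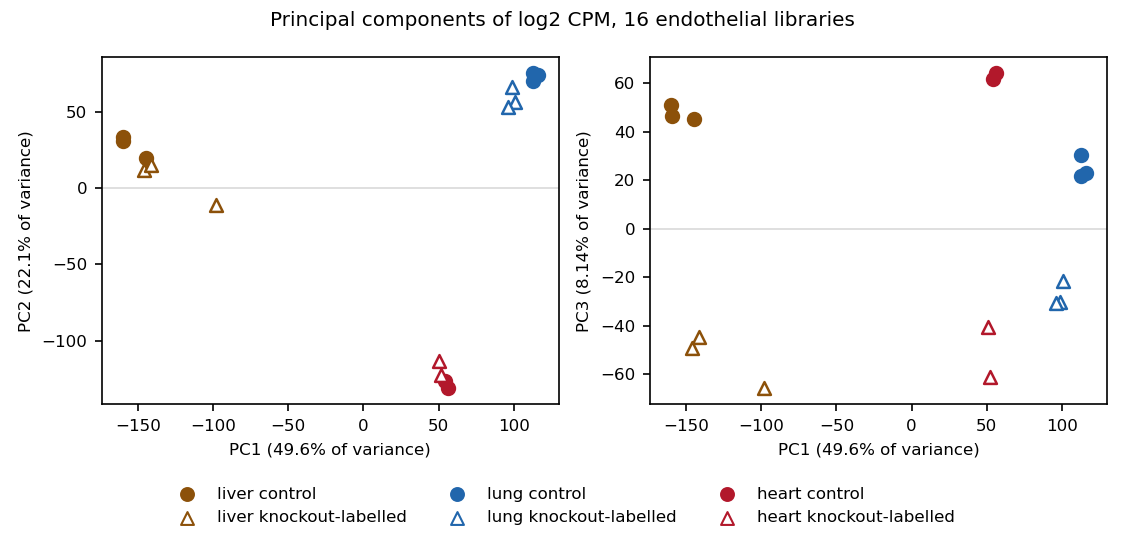
Each point is one library, placed by its scores on principal components 1 and 2 (left) and 1 and 3 (right), with tissue and genotype marked. Component 3 has controls on one side and knockout-labelled libraries on the other in all 3 tissues.

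The targeted genes were read first. Erg lies on chromosome 16 (GRCm38, 95359169 to 95586593, minus strand) and Fli1 on chromosome 9 (32422204 to 32542861, minus strand). Erg in liver fell from 361, 337 and 371 CPM in the controls to 165, 136 and 131 CPM, a log2 change of −1.31 (SE 0.132, adjusted p = 1.54e-05). Lung libraries had 263, 259 and 276 CPM of Erg in the controls and 224, 166 and 164 CPM in the knockout-labelled libraries (log2 −0.52, SE 0.13, adjusted p = 0.0231). Heart had 204 and 229 CPM of Erg against 158 and 155 CPM, which did not pass (log2 −0.47, SE 0.159, adjusted p = 0.0538). For Fli1, liver controls had 123, 113 and 114 CPM and knockout-labelled libraries 144, 125 and 187 CPM (log2 0.38, SE 0.153, adjusted p = 0.1). Fli1 rose in lung, from 76.6, 77.8 and 76.6 CPM to 136, 98.1 and 138 CPM (log2 0.69, SE 0.154, adjusted p = 0.0131). Heart had 198 and 236 CPM of Fli1 in the controls and 207 and 232 CPM in the others (adjusted p = 0.978). Whole-gene counts of Fli1 therefore fell in no tissue, despite the knockout label. Reads outside the deleted part, which the sources used here do not place, count towards both genes. The lung call for Erg ended in a separate fit for lung and without lung control 1, 2 or 3 or knockout-labelled 2 or 3, with adjusted p up to 0.0936, and that for Fli1 without lung control 3 or knockout-labelled 3, with adjusted p up to 0.0533.

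**Figure D2:**
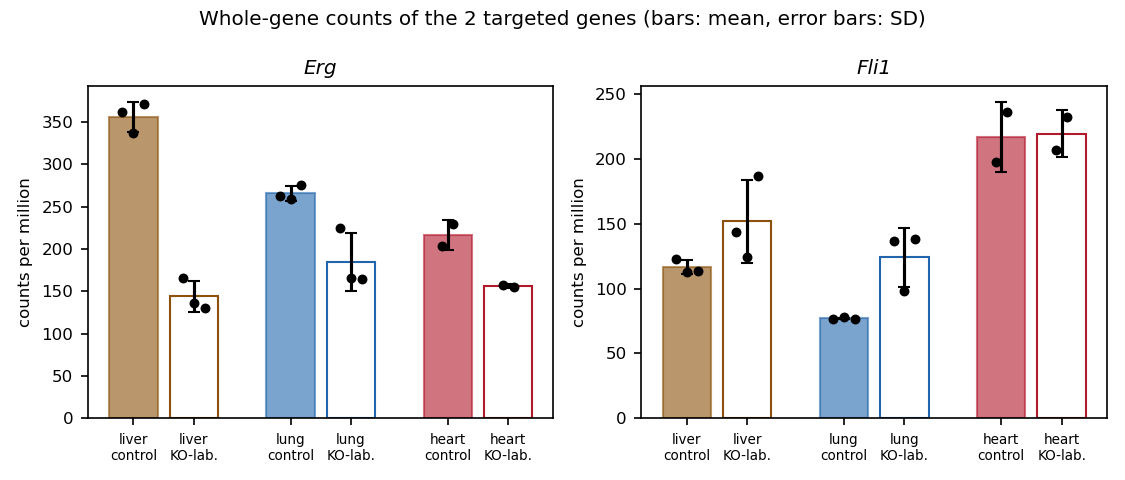
Points are Erg and Fli1 levels (CPM) in each library, with the mean and SD of each tissue and genotype group. Erg is lower in every knockout-labelled library than in every control of its tissue, and Fli1 is not.

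Next to Fli1, 3 genes rose in all 3 tissues. Kcnj1 (chromosome 9, 32372493 to 32399197, plus strand), a renal potassium channel gene, was among the largest rises in each tissue. The gene Gm39317 (32348682 to 32361738, plus strand) went from 0.0554 to 20.9 CPM in liver, from 0.0278 to 11.8 CPM in lung and from 0 to 38.3 CPM in heart (adjusted p = 1.44e-07, 1.2e-06 and 1.17e-06). Kcnj5 (32314707 to 32344350, minus strand), which also encodes a potassium channel, rose from 1.36 to 14.3, 0.169 to 9.78 and 1.51 to 41.4 CPM (adjusted p = 1.24e-05, 4.7e-06 and 2.44e-05). Gm39317 and Kcnj5 were chosen after their values were seen. The next genes on either side were Arhgap32, at log2 0.15, −0.41 and −0.05 in liver, lung and heart, and the ETS gene Ets1, which fell in liver (log2 −0.58, adjusted p = 0.0144) and had log2 −0.11 and −0.09 in lung and heart. Whether reads were counted by strand is not given in the sources used here.

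**Figure D3:**
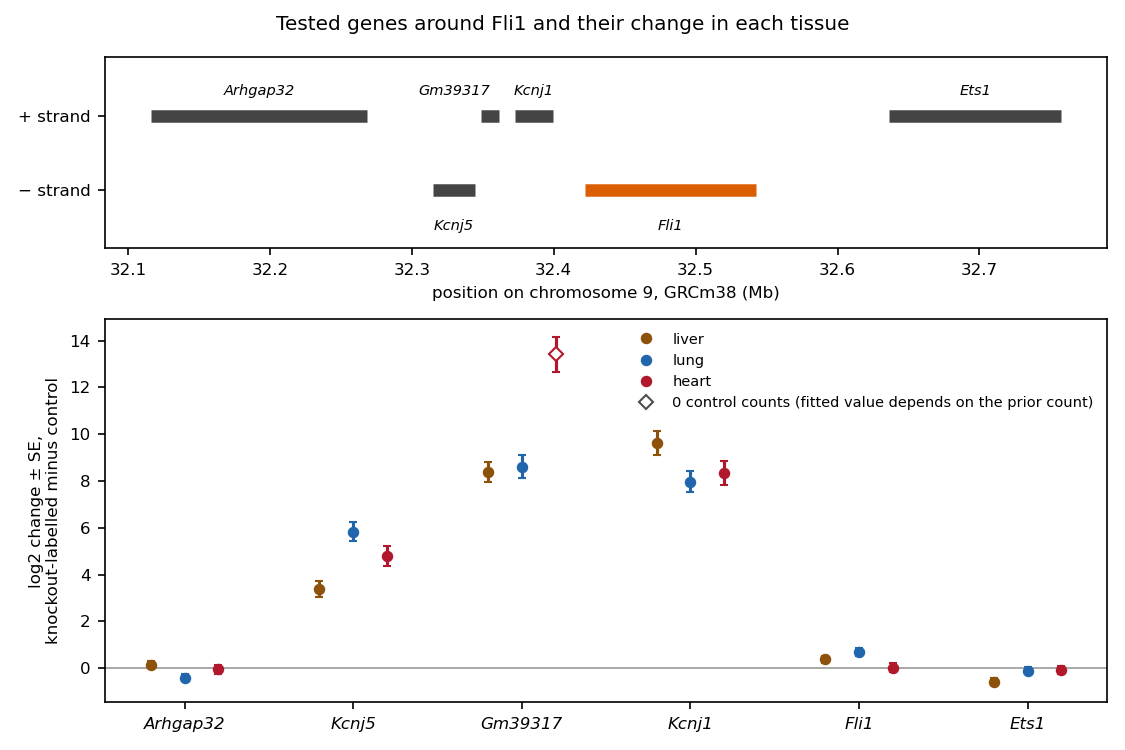
The map shows genes of the Fli1 region on chromosome 9 (position in megabases) and, for each, the log2 change between knockout-labelled and control libraries in liver, lung and heart. The 3 genes beyond the 3 prime end of Fli1 lie far above 0, while Arhgap32 and Ets1 lie near or below it.

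Liver was compared to see what the knockout changes in a sinusoidal endothelium, and genes that fell included Tie1, Nos3, Tek and Clec4g. Tie1, an endothelial receptor tyrosine kinase, fell from 1468 ± 104 to 557 ± 30.02 CPM (log2 −1.40, SE 0.16, adjusted p = 4.28e-05). Nos3, which makes nitric oxide, fell from 168 ± 3.92 to 58.6 ± 16.01 CPM (log2 −1.52, SE 0.191, adjusted p = 9.47e-05). Tek, the angiopoietin receptor, fell from 1077 ± 23.6 to 555 ± 34.3 CPM (adjusted p = 0.00388), and Thbd, the anticoagulant thrombomodulin, from 357 ± 15.9 to 164 ± 57.2 CPM (adjusted p = 0.00322). Clec4g, a lectin of sinusoidal endothelium, fell from 3511 ± 131 to 275 ± 275 CPM (log2 −3.68, adjusted p = 0.00266). Lower too were the tight junction gene Cldn5 (813 ± 45.2 to 543 ± 29.9 CPM, adjusted p = 0.0353) and the adhesion gene Vcam1 (232 ± 45.7 to 83.0 ± 59.8 CPM, adjusted p = 0.0294). The protein C receptor gene Procr rose from 9.10 ± 3.30 to 46.6 ± 49.5 CPM (adjusted p = 0.0161). Among the panel genes that did not pass, Cdh5 (VE-cadherin) had 1981 ± 201 and 1863 ± 327 CPM (adjusted p = 0.786), Pecam1 (CD31) 1454 and 1301, Kdr 5445 and 4651, Vwf 445 and 306, and Emcn 260.3 and 215 CPM.

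In all, 3814 of 19646 genes tested changed in liver, 1875 higher and 1939 lower, of which 1107 and 922 by at least 2-fold. The largest rises with every knockout-labelled library above every control began with Kcnj1, which had 3 counts in the controls together and 26.4 ± 4.52 CPM after (ratio 883, 95% counting interval 302 to 4281, adjusted p = 5.26e-08). Zbtb8b, a zinc finger gene, had 2 control counts and 11.02 ± 4.91 CPM (ratio 544, interval 151 to 4495, adjusted p = 9.44e-06). Further rises were Psg22, a pregnancy-specific glycoprotein gene (0.513 to 213 ± 290 CPM, adjusted p = 0.000574), and the T-cell costimulatory receptor gene Tnfrsf9 (0.121 to 45.0 ± 67.8 CPM, adjusted p = 0.00097). The calcium channel gene Cacna1h rose from 0.141 to 52.5 ± 44.1 CPM (adjusted p = 9.44e-06), and the cathepsin gene Ctsj from 0.111 to 39.2 ± 8.72 CPM (adjusted p = 1.88e-05). Among the largest falls were the chemokine scavenger Ackr4 (113 ± 7.05 to 2.46 ± 1.81 CPM, log2 −5.52, adjusted p = 2.3e-05), the decoy receptor Il13ra2 (50.3 ± 9.44 to 1.23 ± 1.71 CPM, adjusted p = 0.000492) and the collagen gene Col17a1 (10.8 ± 0.707 to 0.278 ± 0.349 CPM, adjusted p = 8.51e-05). The lectin gene Cd209b (25.8 ± 3.09 to 0.779 ± 0.951 CPM, adjusted p = 0.0205), Gna14, a G protein subunit gene (17.8 ± 0.924 to 0.595 ± 0.382 CPM, adjusted p = 8.45e-06), and Tmem35a (14.9 ± 15.6 to 0.580 ± 0.451 CPM, adjusted p = 0.00145) followed. Over all genes, knockout-labelled liver library 3 correlated at 0.968 and 0.964 with the others of its group, which correlated at 0.982 with each other. It stood apart for several genes named above, with 547 CPM of Psg22 against 68.7 and 22.9. Cacna1h had 103.4 CPM there against at most 29.1, and Procr 103 CPM against 27.1 and 9.80. Without library 3 the log2 change was 6.46 for Psg22 (8.68 with it), 5.59 for Tnfrsf9 (8.51 with it) and 7.49 for Cacna1h (8.44 with it). For Procr it was 1.01, and the Procr call then ended (adjusted p = 0.117).

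Of 39 pan-endothelial genes tested in liver, 5 rose, 20 fell and 14 did not pass, with 6 and 22 adjusted over the list alone. By camera the pan-endothelial list had adjusted p = 1.62e-06, and adjusted p = 0.404 with an estimated correlation. Those that fell included the matrix gene Mmrn2 (1228 ± 141 to 343 ± 53.9 CPM) and Ushbp1 (1233 ± 145 to 205 ± 85.5 CPM). The 28 sinusoidal markers had 1 rise and 17 falls, or 1 and 19 adjusted over the list alone, with a median log2 change of −1.20. The sinusoidal list had a camera adjusted p = 1.2e-10, and adjusted p = 0.164 with an estimated correlation. Kit, a receptor tyrosine kinase gene, fell from 778 ± 148 to 137 ± 77.2 CPM, Ntn4, encoding a netrin, from 625 ± 96.8 to 176 ± 107 CPM, and Gpr182, a chemokine-binding receptor gene, from 3118 ± 156 to 1226 ± 281 CPM. Among 23 scavenger and endocytic receptors, 1 rose and 10 fell (2 and 11 adjusted over the list alone), such as Scarf1 (356 ± 12.9 to 174 ± 22.8 CPM) and the clathrin adaptor Dab2 (779 ± 10.7 to 256 ± 66.0 CPM). By camera the scavenger receptor list had adjusted p = 2.88e-05, and adjusted p = 0.268 with an estimated correlation. Junction genes numbered 25, with 2 higher and 10 lower (3 and 11 adjusted over the list alone). The junction list had a camera adjusted p = 0.0342, and adjusted p = 0.658 with an estimated correlation. Jam2, a junctional adhesion molecule, fell from 763 ± 65.2 to 132 ± 52.1 CPM and the gap junction gene Gja5 from 6.22 ± 2.703 to 0.631 ± 0.0699 CPM, while Plvap, of fenestral diaphragms, rose from 637 ± 35.1 to 2709 ± 375 CPM (adjusted p = 0.000311). VEGF and angiopoietin genes (25) had 3 rises and 10 falls, 6 and 10 adjusted over the list alone, with a median of −0.19 but a mean of 0.18. By camera the VEGF and angiopoietin list had adjusted p = 0.0496, and adjusted p = 0.459 with an estimated correlation. The VEGF receptor Flt1 fell from 1217 ± 147 to 409 ± 114 CPM and the apelin receptor Aplnr rose from 1.93 ± 1.03 to 13.96 ± 10.3 CPM (adjusted p = 0.000163 and 0.0015).

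Antigen presentation genes fell in liver in 20 of 22 cases and none rose (21 adjusted over the list alone), with a median of −1.58. The antigen presentation list had a camera adjusted p = 7.23e-16, and adjusted p = 0.268 with an estimated correlation. The class I gene H2-K1 fell from 2952 ± 131 to 872 ± 37.98 CPM, H2-Q6 from 452 ± 17.1 to 58.3 ± 9.11 CPM, and their transactivator Nlrc5 from 66.8 ± 10.3 to 19.1 ± 1.82 CPM. Interferon-response genes moved the same way, 22 of 37 lower and 1 higher (27 and 1 adjusted over the list alone), as for the guanylate-binding proteins Gbp2 (72.5 ± 5.64 to 14.6 ± 3.50 CPM) and Gbp5 (46.1 ± 8.56 to 13.3 ± 2.16 CPM). By camera the interferon list had adjusted p = 5.87e-11, and adjusted p = 0.459 with an estimated correlation. Beside these, the 19 pan-leukocyte markers had a median of −0.95 with 1 fall, the granzyme gene Gzmb (1.11 to 0.124 CPM), and 0 adjusted over the list alone. The pan-leukocyte list had a camera adjusted p = 0.013, and adjusted p = 0.944 with an estimated correlation. Complement genes had 2 rises and 4 falls among 20, 2 and 6 adjusted over the list alone, with C1ra down from 83.2 ± 7.83 to 29.4 ± 2.34 CPM. By camera the complement list had adjusted p = 0.0481, and adjusted p = 0.944 with an estimated correlation.

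Higher in liver were hypoxia and glycolysis genes, with 14 of 24 up and 0 down (18 adjusted over the list alone). The hypoxia and glycolysis list had a camera adjusted p = 2.14e-08, and adjusted p = 0.404 with an estimated correlation. The stress gene Ddit4 rose from 71.5 ± 9.87 to 616 ± 172 CPM, the oxygen sensor Egln3 from 1.61 ± 0.342 to 42.5 ± 25.1 CPM and the glucose transporter Slc2a1 from 5.39 ± 1.14 to 71.9 ± 48.3 CPM. Basement membrane and matrix genes rose in 16 and fell in 4 of 34 cases (18 and 6 adjusted over the list alone), with fibrillin Fbn1 up from 22.4 ± 5.90 to 163 ± 20.1 CPM and laminin Lama4 down from 384 ± 73.5 to 124 ± 15.4 CPM. By camera the matrix list had adjusted p = 0.019, and adjusted p = 0.459 with an estimated correlation. Of 18 stellate and cholangiocyte markers, 4 rose and 14 did not pass (4 up adjusted over the list alone), led by the growth factor gene Hgf (107 ± 20.4 to 688 ± 120 CPM). The stellate and cholangiocyte list had a camera adjusted p = 0.0481, and adjusted p = 0.944 with an estimated correlation. Of 26 p53 and arrest genes, 7 rose and 4 fell (8 and 4 adjusted over the list alone), with Gadd45a at 6.93 ± 2.11 and 58.5 ± 30.6 CPM, the cell cycle inhibitor gene Cdkn1a at 59.3 ± 19.7 and 188 ± 51.7 CPM, and the death receptor gene Fas down from 82.9 ± 10.3 to 27.0 ± 2.05 CPM. By camera the p53 and arrest list had adjusted p = 0.0481, and adjusted p = 0.404 with an estimated correlation. Immediate early and dissociation genes rose in 7 of 31 cases and fell in 0 (7 adjusted over the list alone), as for Nr4a1 (73.0 ± 48.4 to 426 ± 169 CPM). The immediate early list had a camera adjusted p = 0.0304, and adjusted p = 0.991 with an estimated correlation. Hepatocyte transcripts were lower, with 5 of 29 down and 1 up, as many adjusted over the list alone, as for Apoa2 (68.6 ± 52.4 to 18.2 ± 3.84 CPM). By camera the hepatocyte list had adjusted p = 0.000731, and adjusted p = 0.944 with an estimated correlation.

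In all, 15 of the 45 lists passed in liver (5 higher, 10 lower), 7 in a fit of liver alone and 0 with an estimated correlation. Leaving out 1 library ended the calls for Cldn5 (any liver library, adjusted p up to 0.109), Gzmb (any liver library, up to 0.118), Vcam1 (control 1 or 3, knockout-labelled 1 or 2, up to 0.101), Cd209b (control 3, knockout-labelled 2 or 3), Procr (control 2 or 3, knockout-labelled 3), hepatocyte markers (control 3, 0.0522), matrix genes (control 2, 0.0551), junctions (control 1, knockout-labelled 3), pan-leukocyte markers (knockout-labelled 3), p53 genes (control 2 or 3, knockout-labelled 1, up to 0.14), complement (control 3, 0.312, knockout-labelled 3 and some lung libraries), stellate and cholangiocyte markers (control 1 or 2, knockout-labelled 3, up to 0.309, and some lung libraries), VEGF genes (control 1 or knockout-labelled 2, up to 0.225, and some lung libraries) and immediate early genes (control 2, or knockout-labelled 3, adjusted p = 0.998, with the direction turned).

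Lung was compared to see what the knockout changes in an alveolar endothelium, and the receptor genes Tek and Tie1 were among those that fell. Tek fell from 1440 ± 95.7 to 411 ± 159 CPM (log2 −1.81, SE 0.203, adjusted p = 0.000171) and Tie1 from 1591 ± 32.4 to 775 ± 164 CPM (log2 −1.04, adjusted p = 0.00137). Thbd fell from 4055 ± 470 to 2107 ± 141 CPM (adjusted p = 0.0189) and Nos3 from 82.9 ± 11.4 to 48.2 ± 7.77 CPM (adjusted p = 0.0201). Emcn, a sialomucin of veins and capillaries, rose from 178 ± 10.6 to 447 ± 107 CPM (log2 1.33, SE 0.177, adjusted p = 0.000589). Cdh5 had 3499 ± 261 and 2899 ± 519 CPM, Pecam1 2592 and 1719 (adjusted p = 0.0576), Kdr 1348 and 1321, Vwf 2738 and 1951, Cldn5 3038 and 2264, Vcam1 94.9 and 114, and Procr 8.45 and 30.6 CPM, none past the threshold.

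In lung 1663 genes changed, 855 higher and 808 lower, of which 423 and 428 by at least 2-fold. The largest rises with libraries fully separated were Kcnj1 (0.0611 to 16.2 ± 3.76 CPM, adjusted p = 6.9e-07), Lancl3 (0.631 to 44.0 ± 31.2 CPM, adjusted p = 6.41e-05) and Clca3a1, an anion channel regulator gene (16.1 ± 3.89 to 672 ± 292 CPM, log2 5.38, adjusted p = 7.51e-06). Acetylcholinesterase, Ache, rose from 0.690 to 22.5 ± 15.8 CPM (adjusted p = 0.000171), Adam23 from 8.44 ± 2.83 to 200.2 ± 133 CPM (adjusted p = 0.00029) and the adhesion gene Flrt3 from 3.49 ± 0.865 to 79.4 ± 58.7 CPM (adjusted p = 0.00353). The largest falls included 3 class II antigen presentation genes, the invariant chain Cd74 (635 ± 455 to 25.3 ± 7.81 CPM, adjusted p = 0.000735), H2-Eb1 (214 ± 114 to 11.5 ± 2.72 CPM, adjusted p = 0.000589) and the class II transactivator Ciita (43.5 ± 9.89 to 3.12 ± 0.455 CPM, adjusted p = 0.000233). Ackr4 fell from 38.6 ± 15.3 to 2.34 ± 1.18 CPM (adjusted p = 0.000677), the complement gene Hc from 52.1 ± 7.39 to 3.74 ± 4.39 CPM (adjusted p = 0.0064) and Hpcal4 from 19.8 ± 5.11 to 1.13 ± 0.244 CPM (adjusted p = 0.00153).

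Of 39 pan-endothelial genes tested in lung, 3 rose and 20 fell, 3 and 27 adjusted over the list alone, with a median of −0.68. The pan-endothelial list had a camera adjusted p = 7.99e-12, and adjusted p = 0.199 with an estimated correlation. Examples were the proton-sensing receptor gene Gpr4 (50.9 ± 4.98 to 23.4 ± 3.74 CPM), Cyyr1 (774 ± 78.0 to 305 ± 58.2 CPM) and the junction regulator Rasip1 (419 ± 25.7 to 179 ± 30.9 CPM). Arterial markers fell in 6 and rose in 1 of 24 cases (14 and 4 adjusted over the list alone), with Gja5 down from 35.7 ± 3.95 to 8.86 ± 1.29 CPM and Ltbp4 from 783 ± 50.4 to 229 ± 47.4 CPM. By camera the arterial list had adjusted p = 4.52e-05, and adjusted p = 0.416 with an estimated correlation. In the Notch pathway 4 of 19 fell and 0 rose, 4 adjusted over the list alone, including the receptor Notch1 (616 ± 120 to 281 ± 92.5 CPM) and the glycosyltransferase Mfng (141 ± 16.3 to 54.4 ± 8.67 CPM). The Notch list had a camera adjusted p = 0.0285, and adjusted p = 0.625 with an estimated correlation. Junction genes had 4 falls and 0 rises among 25 (6 and 1 adjusted over the list alone), as for Esam (831 ± 15.7 to 413 ± 72.6 CPM). By camera the junction list had adjusted p = 0.000283, and adjusted p = 0.337 with an estimated correlation. Among 25 VEGF and angiopoietin genes, 4 rose and 8 fell, 5 and 11 adjusted over the list alone. The VEGF and angiopoietin list had a camera adjusted p = 0.0211, and adjusted p = 0.337 with an estimated correlation. The ligand Angpt2, which antagonises Tek, rose from 42.7 ± 2.45 to 537 ± 344 CPM, and the Notch ligand Dll4 fell from 344 ± 55.5 to 131 ± 35.0 CPM (adjusted p = 6.41e-05 and 0.00264). Lung endothelial markers as a list did not pass (1 up and 7 down of 32, 3 and 10 adjusted over the list alone, camera adjusted p = 0.27), though the sodium channel subunit Scn3b fell from 254 ± 28.0 to 62.7 ± 21.9 CPM and Scn7a rose from 1170 ± 98.6 to 4054 ± 1881 CPM (adjusted p = 0.00284 and 0.00148).

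Antigen presentation genes fell in lung in 16 of 22 cases and 0 rose (20 adjusted over the list alone, median −1.08), as for H2-DMa (38.6 ± 20.8 to 3.89 ± 0.506 CPM), which loads peptides on class II molecules. By camera the antigen presentation list had adjusted p = 1.11e-18, and adjusted p = 0.199 with an estimated correlation. Interferon-response genes fell in 12 of 37 cases and 0 rose, 24 adjusted over the list alone, with Gbp5 down from 56.4 ± 8.64 to 11.1 ± 3.51 CPM. The interferon list had a camera adjusted p = 7.13e-13, and adjusted p = 0.406 with an estimated correlation. With them, the 24 lung epithelial markers had 12 falls and 0 rises (17 adjusted over the list alone) and a median of −1.73 (camera adjusted p = 1.11e-18), the 1 list past the threshold with an estimated correlation (adjusted p = 0.00303). Surfactant genes Sftpa1 and Sftpb fell from 311 ± 44.1 to 35.8 ± 14.1 CPM and from 366 ± 59.2 to 47.8 ± 15.6 CPM (adjusted p = 6.41e-05 and 0.000714). NF-kB genes rose in 5 of 23 cases and fell in 0 (5 and 1 adjusted over the list alone), including Nfkb1 itself (204 ± 6.53 to 299 ± 39.3 CPM) and Ninj1 (36.0 ± 3.75 to 64.6 ± 6.33 CPM). By camera the NF-kB list had adjusted p = 0.0135, and adjusted p = 0.792 with an estimated correlation. Basement membrane and matrix genes rose in 10 and fell in 1 of 34 cases, 12 and 4 adjusted over the list alone, with laminin Lamc1 up from 177 ± 35.1 to 586 ± 38.5 CPM and collagen Col15a1 down from 57.3 ± 25.6 to 11.5 ± 4.13 CPM. The matrix list had a camera adjusted p = 0.00377, and adjusted p = 0.337 with an estimated correlation. Platelet markers rose in 4 of 15 cases (10 adjusted over the list alone, with 1 fall), led by the integrin Itga2b (9.86 ± 1.16 to 41.2 ± 4.5 CPM). By camera the platelet list had adjusted p = 0.000212, and adjusted p = 0.337 with an estimated correlation. Erythrocyte markers had 0 of 11 past the threshold, 5 higher adjusted over the list alone, and a median of 2.20, with globin Hba-a1 at 9.90 ± 2.07 and 62.2 ± 63.3 CPM. The erythrocyte list had a camera adjusted p = 0.00377, and adjusted p = 0.625 with an estimated correlation.

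In lung 12 lists passed, 4 higher and 8 lower, and the number of genes changed was 1033, 988 and 917 without lung control 1, 2 and 3. Leaving out 1 library ended the calls for Notch (control 2 or 3, knockout-labelled 2 or 3, adjusted p up to 0.156), NF-kB (control 2, knockout-labelled 1 or 3, up to 0.0788), VEGF (control 2, knockout-labelled 2 or 3, up to 0.0626), Thbd (control 2 or 3, knockout-labelled 1 or 2, up to 0.0732) and Nos3 (control 1 or 3, knockout-labelled 2, up to 0.0795).

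Heart was compared to see what the knockout changes in a continuous capillary endothelium, and the receptor genes Kdr, Tie1 and Tek fell. Kdr, the main VEGF receptor, fell from 3073 ± 333 to 1118 ± 248 CPM (log2 −1.46, SE 0.261, adjusted p = 0.00184). Tie1 fell from 1720 ± 66.6 to 662 ± 104 CPM (log2 −1.38, adjusted p = 0.000442), Tek from 599 ± 12.3 to 338 ± 10.4 CPM (adjusted p = 0.0296) and Thbd from 1087 ± 253 to 529 ± 66.9 CPM (adjusted p = 0.0185). Procr rose from 13.3 ± 1.27 to 103 ± 29.2 CPM and Vcam1 from 81.9 ± 12.4 to 254 ± 60.8 CPM (adjusted p = 0.0169 and 0.049). Cdh5 had 2723 ± 133 and 2076 ± 222 CPM (adjusted p = 0.243), Pecam1 1893 and 1944, Vwf 560.0 and 289, Nos3 380 and 257, Emcn 387 and 286, and Cldn5 380 and 516 CPM, none past the threshold.

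In heart 3786 genes changed, 2001 higher and 1785 lower, of which 1301 and 894 by at least 2-fold. The embryonic globin Hbb-y had 1 control count and 25.5 ± 14.3 CPM after (ratio 1782, interval 319.9 to 70400, adjusted p = 0.00383), and the chromatin gene Hmga2 had 2 control counts and 13.1 ± 3.49 CPM (ratio 466, interval 129 to 3843, adjusted p = 0.000247). Kcnj1 rose from 0.140 to 47.0 ± 1.89 CPM (log2 8.34, adjusted p = 1.17e-06), Sh2d5 from 0.783 to 95.2 ± 74.7 CPM (adjusted p = 0.000119), Disp2 from 0.226 to 22.9 ± 9.42 CPM (adjusted p = 4.42e-05) and the growth cone gene Gap43 from 0.623 to 41.8 ± 8.59 CPM (adjusted p = 0.00015). Falls were led by Nepn, a small proteoglycan gene (16.8 ± 2.75 to 0.125 ± 0.0314 CPM, adjusted p = 5.82e-05), the cytochrome Cyp1a1 (16.4 ± 8.91 to 0.162 ± 0.0125 CPM, adjusted p = 0.00375) and Sez6 (10.2 ± 1.47 to 0.113 ± 0.0567 CPM, adjusted p = 0.000652). The actin-binding Coro6 fell from 488 ± 55.1 to 16.4 ± 0.326 CPM (adjusted p = 0.00144), Clmn from 46.2 ± 3.11 to 2.21 ± 0.0529 CPM (adjusted p = 7.27e-05) and Krt222 from 10.2 ± 0.231 to 0.485 ± 0.144 CPM (adjusted p = 0.00061).

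Of 39 pan-endothelial genes tested in heart, 3 rose and 16 fell (3 and 21 adjusted over the list alone), such as Ushbp1 (1690 ± 82.2 to 120.4 ± 23.8 CPM) and the guidance receptor Robo4 (757 ± 3.23 to 149 ± 14.3 CPM). By camera the pan-endothelial list had adjusted p = 8.39e-07, and adjusted p = 0.219 with an estimated correlation. Heart endothelial markers fell in 11 and rose in 2 of 28 cases, 16 and 2 adjusted over the list alone, with a median of −1.33. The heart endothelial list had a camera adjusted p = 1.47e-08, and adjusted p = 0.203 with an estimated correlation. The nucleoside transporter Slc28a2 fell from 691 ± 97.1 to 39.9 ± 4.72 CPM, the lipase Mgll from 1551 ± 146 to 323 ± 76.3 CPM and Tcf15, a regulator of fatty-acid uptake, from 293 ± 45.7 to 21.9 ± 7.27 CPM. Among 25 VEGF and angiopoietin genes 2 rose and 9 fell (3 and 9 adjusted over the list alone), with Flt1 down from 2218 ± 254 to 1057 ± 217 CPM. By camera the VEGF and angiopoietin list had adjusted p = 0.00477, and adjusted p = 0.203 with an estimated correlation. Junction genes had 3 rises and 8 falls among 25, 4 and 8 adjusted over the list alone, with the scaffold Afdn down from 1115 ± 85.2 to 233 ± 21.7 CPM and Nectin2 up from 24.5 ± 1.66 to 53.8 ± 3.09 CPM. The junction list had a camera adjusted p = 0.0357, and adjusted p = 0.4 with an estimated correlation. Antigen presentation genes fell in 12 and rose in 1 of 22 cases, 12 and 1 adjusted over the list alone, with H2-Q7 down from 233 ± 47.8 to 54.6 ± 1.05 CPM. By camera the antigen presentation list had adjusted p = 2.14e-06, and adjusted p = 0.303 with an estimated correlation. Interferon-response genes fell in 15 and rose in 1 of 37 cases, 17 and 1 adjusted over the list alone, as for Gbp5 (121 ± 15.01 to 24.5 ± 8.79 CPM) and the antiviral gene Rsad2 (239 ± 34.8 to 49.0 ± 9.93 CPM). The interferon list had a camera adjusted p = 2.67e-07, and adjusted p = 0.4 with an estimated correlation.

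Mesenchymal genes rose in heart in 17 of 31 cases and 1 fell, 20 and 1 adjusted over the list alone. By camera the mesenchymal list had adjusted p = 5.06e-10, and adjusted p = 0.0844 with an estimated correlation. The intermediate filament gene Vim rose from 1135 ± 49.7 to 5390 ± 402 CPM and the fibronectin receptor gene Itga5 from 218 ± 50.5 to 707 ± 217 CPM. Matrix and basement membrane genes rose in 10 and fell in 1 of 34 cases (14 and 1 adjusted over the list alone), with the membrane protease Mmp14 at 30.2 ± 1.41 and 278 ± 48.3 CPM and its inhibitor Timp1 at 1.97 ± 0.285 and 63.7 ± 22.0 CPM. The matrix list had a camera adjusted p = 8.2e-05, and adjusted p = 0.203 with an estimated correlation. Hypoxia and glycolysis genes rose in 16 of 24 cases and 0 fell, 19 adjusted over the list alone, as for Pgk1 (28.5 ± 0.186 to 172 ± 10.4 CPM) and Eno1 (91.7 ± 2.81 to 421 ± 47.8 CPM). By camera the hypoxia and glycolysis list had adjusted p = 2.59e-10, and adjusted p = 0.203 with an estimated correlation. Anticoagulant and fibrinolytic genes rose in 11 and fell in 3 of 22 cases, 12 and 4 adjusted over the list alone. Their median was 0.92, or 0.73 with genes that had no count in a group at their bound. The anticoagulant list had a camera adjusted p = 0.0116, and adjusted p = 0.22 with an estimated correlation. Their plasminogen receptor subunit Anxa2 rose from 346 ± 11.3 to 1294 ± 38.4 CPM. Unfolded protein response genes had 5 rises and 1 fall among 26, 6 and 1 adjusted over the list alone, with Manf up from 32.3 ± 1.43 to 63.7 ± 4.45 CPM. By camera the unfolded protein list had adjusted p = 0.016, and adjusted p = 0.488 with an estimated correlation. Proliferation genes rose in 4 of 37 cases and 0 fell, 2 adjusted over the list alone, as for the replication licensing gene Mcm2 (19.5 ± 0.193 to 46.7 ± 7.55 CPM). The proliferation list had a camera adjusted p = 1.93e-05, and adjusted p = 0.553 with an estimated correlation.

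Leukocyte adhesion and chemokine genes rose in heart in 14 and fell in 2 of 30 cases (17 and 3 adjusted over the list alone), with a median of 2.40, or 2.14 at the bound. By camera the adhesion and chemokine list had adjusted p = 0.000154, and adjusted p = 0.303 with an estimated correlation. The cytokine Il1a rose from 0.689 ± 0.318 to 26.8 ± 12.8 CPM and the monocyte chemokine Ccl2 from 4.64 ± 0.370 to 138 ± 68.5 CPM. NF-kB genes rose in 7 of 23 cases, 7 adjusted over the list alone, and 0 fell, with Tnfaip2 up from 22.9 ± 1.85 to 291 ± 73.7 CPM. The NF-kB list had a camera adjusted p = 3.02e-05, and adjusted p = 0.303 with an estimated correlation. Complement genes had 4 rises and 1 fall among 20, 10 and 1 adjusted over the list alone, with clusterin Clu up from 103 ± 7.41 to 556 ± 65.7 CPM. By camera the complement list had adjusted p = 0.0028, and adjusted p = 0.4 with an estimated correlation. Transcription factors and receptors of blood cell formation rose in 9 of 19 cases and 0 fell, 13 and 1 adjusted over the list alone, as for Hhex (42.3 ± 12.6 to 186 ± 27.3 CPM) and Runx1 (0.582 to 6.11 ± 1.73 CPM). The blood cell formation list had a camera adjusted p = 0.000543, and adjusted p = 0.203 with an estimated correlation. Markers of other cell types moved in the same libraries. Pan-leukocyte markers rose in 9 of 19 cases and 0 fell, 9 adjusted over the list alone, as for Laptm5 (4.51 ± 2.32 to 26.9 ± 4.54 CPM). By camera the pan-leukocyte list had adjusted p = 0.000681, and adjusted p = 0.303 with an estimated correlation. Macrophage and neutrophil markers rose in 10 of 27, 16 adjusted over the list alone, with a median of 3.11, or 2.998 at the bound, as for Fcer1g (2.07 to 11.02 ± 4.45 CPM). The macrophage and neutrophil list had a camera adjusted p = 3.58e-05, and adjusted p = 0.203 with an estimated correlation. Lung epithelial markers rose in 16 and fell in 1 of 24 cases, 17 and 1 adjusted over the list alone, with a median of 4.04, or 3.65 at the bound, as for Sftpa1 (0.295 ± 0.171 to 16.8 ± 3.63 CPM). By camera the lung epithelial list had adjusted p = 4.31e-05, and adjusted p = 0.179 with an estimated correlation. Cardiomyocyte markers fell in 7 and rose in 1 of 29 cases, as many adjusted over the list alone, as for myoglobin Mb (49.8 ± 14.2 to 11.7 ± 1.27 CPM). The cardiomyocyte list had a camera adjusted p = 0.000459, and adjusted p = 0.32 with an estimated correlation.

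In heart 20 lists passed, 13 higher and 7 lower, 0 of them with an estimated correlation, and the number of genes changed was 1911 and 1883 without heart control 1 and 2 and 1788 without knockout-labelled library 1. Leaving out 1 heart library ended the calls for Tek (any of the 4, adjusted p up to 0.144), Vcam1 (any of the 4, up to 0.22), Procr (control 1 or 2, knockout-labelled 1, up to 0.116), Thbd (control 2, knockout-labelled 1, up to 0.152), Flt1 (control 2, knockout-labelled 1, up to 0.108), Laptm5 (control 1, 0.0907), Manf (control 2, 0.0531), Mb (control 2, 0.0737) and junctions (control 2, 0.0992), and limma voom ended that for Cyp1a1 (0.178).

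**Figure D4:**
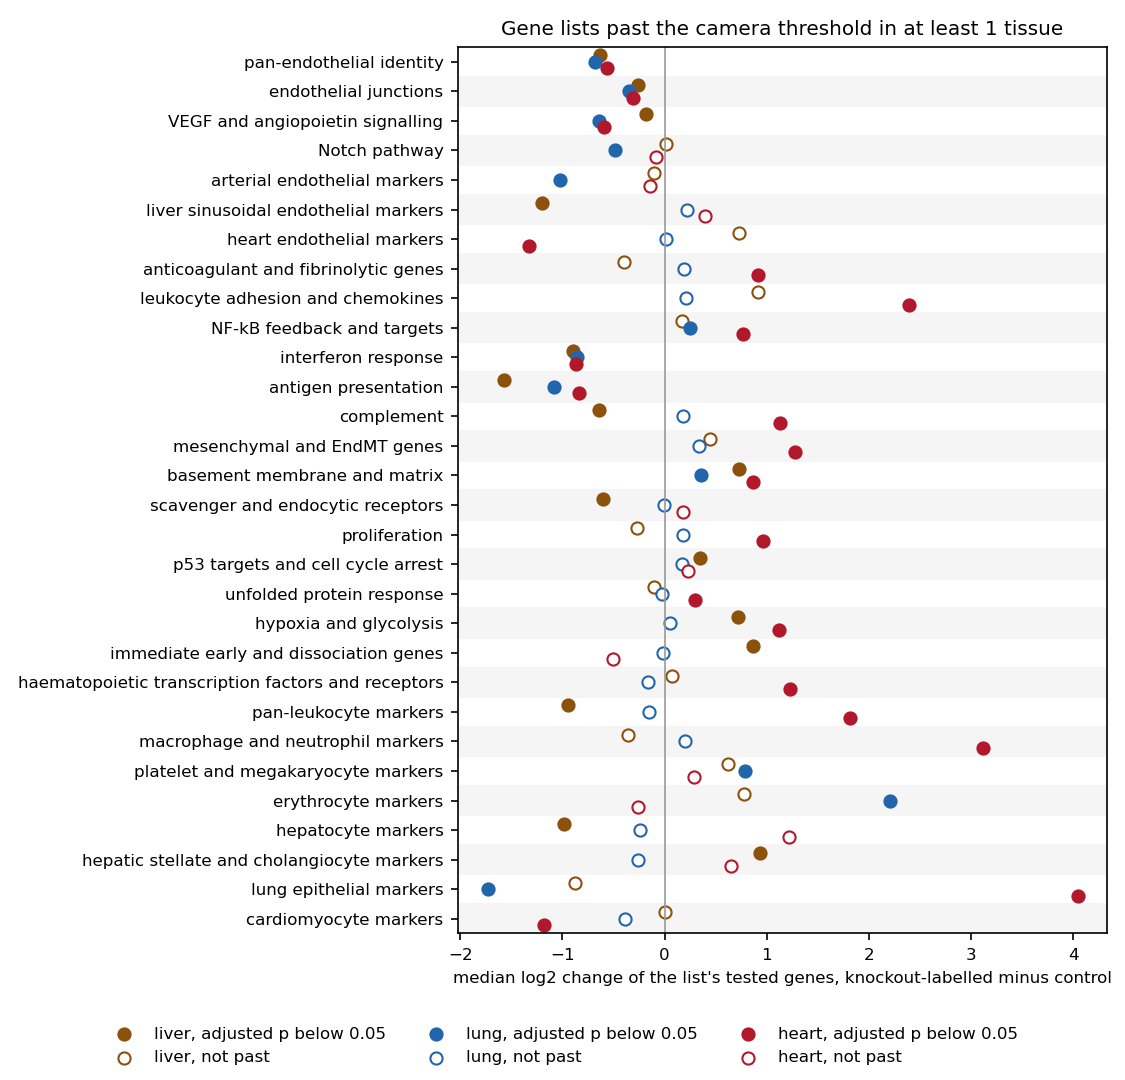
Each point is the median log2 change of one list of genes in liver, lung or heart, with those past the threshold of the camera test marked. Antigen presentation and interferon lists lie below 0 in all 3 tissues, while lung epithelial markers lie below 0 in lung and above 0 in heart.

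The same direction in all 3 tissues was found for 436 genes, 200 higher and 236 lower, against 15.6 expected from independent calls. Tie1, Tek, Thbd, Ltbp4 (a TGF-beta binding protein), the natriuretic peptide receptor Npr1 and the death ligand Tnfsf10 were among those lower in all 3, and the urokinase gene Plau, Hhex and Itga2b among those higher. For instance, Ltbp4 fell from 3290 ± 316 to 208 ± 88.7 CPM in liver and from 4290 ± 261 to 977 ± 278 CPM in heart, and Hhex, a homeobox gene, rose from 66.3 ± 7.56 to 262 ± 40.2 CPM in liver and from 53.4 ± 3.2 to 180 ± 34.7 CPM in lung. These examples were chosen after their values were seen. Liver and lung shared 345 higher and 372 lower genes (81.6 and 79.8 from independent calls), liver and heart 604 and 630 (191 and 176), and lung and heart 340 and 365 (87.1 and 73.4). In these pairs 75, 170 and 101 genes went opposite ways (162, 368 and 160 from independent calls). The calls come from the same fit with a shared spread per gene, and genes differ in how easily a change is found. More overlap than from independent calls can thus arise without a shared response. Without lung control 2 or 3 the number shared by all 3 tissues was 286 or 274, and 180 were at least 2-fold in each.

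The knockout effect itself was compared between tissues by the interaction of tissue and genotype. Erg counts fell more in liver than in lung or heart (differences 0.78 and 0.84, adjusted p = 0.0214 and 0.0226). Both calls ended when certain libraries were left out. The extent of the deletion may thus differ between tissues, and these comparisons cannot separate it from the tissue. Emcn rose in lung, and its log2 change was 1.60 above that in liver (adjusted p = 0.00179), while heart against lung gave a difference of −1.77 (adjusted p = 0.00267). Kdr fell in heart, with a difference of −1.23 from liver (adjusted p = 0.035) and −1.43 from lung (adjusted p = 0.0223). Log2 changes of sinusoidal markers were higher in lung than in liver (median difference 1.45, camera adjusted p = 3.89e-07, adjusted p = 0.441 with an estimated correlation). In lung their median was 0.22 (camera adjusted p = 0.659). Those of heart endothelial markers were lower in heart than in lung (median difference −1.24, camera adjusted p = 7.39e-06, adjusted p = 0.296 with an estimated correlation), with a lung median of 0.02 (camera adjusted p = 0.727). Most sinusoidal markers were far lower in lung controls than in liver controls (Oit3 0.247 against 2866 CPM), and most heart markers lower than in heart controls. Both lists thus had less room to fall in lung, and whether their fall is particular to a tissue is not decided. Log2 changes of hypoxia and glycolysis genes were higher in heart than in lung (median difference 1.47, camera adjusted p = 7.94e-09, adjusted p = 0.0654 with an estimated correlation), as were those of mesenchymal genes (0.94, camera adjusted p = 5.28e-06, adjusted p = 0.116 with an estimated correlation). Lung epithelial markers also differed between heart and lung (17 of 24, median difference 6.64, camera adjusted p = 6.34e-13, adjusted p = 0.00804 with an estimated correlation). The effect differed for 1219 genes between lung and liver (614 with a higher value in lung), 1635 between heart and liver (908 higher in heart) and 1257 between heart and lung (752 higher in heart). Leaving out 1 library took these, at the lowest, to 807 without lung control 3, 711 without heart control 1 and 467 without knockout-labelled heart library 1. The Kdr calls ended without heart control 1 or knockout-labelled heart library 1, among other libraries (adjusted p up to 0.137 against liver and 0.112 against lung).

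Tissues were also compared within each genotype to see which tissue differences the knockout leaves, and cell purity and tissue cannot be separated in these. In controls, Bmp2, a morphogen of the liver sinusoid, had 1999 ± 108 CPM in liver against 5.95 ± 0.533 in lung and 8.40 ± 1.91 in heart (adjusted p = 1.15e-10 and 1.93e-09). Prx had 833 ± 116 CPM in lung against 6.33 in liver and 12.1 in heart (adjusted p = 2.16e-11 and 9.82e-10), and the transcription factor gene Foxf1 1606 ± 222 against 0.890 and 4.15 CPM. Slc28a2 had 691 ± 97.1 CPM in heart against 1.15 in liver and 0.966 in lung (adjusted p = 7.78e-09 and 1.62e-08). In knockout-labelled libraries Bmp2 had 1078 ± 53.9 CPM in liver against 5.49 in lung and 27.6 in heart (adjusted p = 1.69e-10 and 4.12e-08). Prx then had 954 ± 131 CPM in lung against 7.19 and 20.9, and Slc28a2 39.9 ± 4.72 CPM in heart against 0.698 and 0.760 in liver and lung (adjusted p = 2.33e-07 and 3.44e-07).

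Sinusoidal markers were lower in control lung than in control liver in 26 of 28 cases (median −7.02, camera adjusted p = 1.12e-18, adjusted p = 0.0117 with an estimated correlation) and in 24 of 28 between knockout-labelled libraries, with 2 higher (median −4.97, adjusted p = 6.13e-16, adjusted p = 0.0275 with an estimated correlation). Lung endothelial markers were higher in control lung than in control liver in 25 of 32 cases and lower in 2 (median 4.44, adjusted p = 1.55e-11, adjusted p = 0.0316 with an estimated correlation), and higher in 24 and lower in 1 between knockout-labelled libraries (median 3.32, adjusted p = 1.47e-12, adjusted p = 0.0275 with an estimated correlation). Heart endothelial markers were higher in control heart than in control lung in 18 of 28 cases (median 2.48, adjusted p = 7.55e-14, adjusted p = 0.0724 with an estimated correlation), against 16 higher and 1 lower after (median 1.78, adjusted p = 2.13e-06, adjusted p = 0.144 with an estimated correlation). Genes that differed numbered 9238 between lung and liver (4831 higher in lung), 9359 between heart and liver (4666 higher in heart) and 5800 between heart and lung (2644 higher in heart) in controls. In knockout-labelled libraries they numbered 7970 (4039 higher), 7327 (3570 higher) and 6102 (3030 higher). Without heart control 1 the heart and lung controls differed at 3467 genes, and without knockout-labelled heart library 1 the counts were 4743 against liver and 3482 against lung.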

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

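All tests of explanations in this part were chosen after the results they concern had been seen. For sex, the covariate too was chosen after seeing the data, but its effect on antigen presentation had not been seen. The genes given first for each pair of tissues stand out because the knockout effect differed between tissues by an interaction test (edgeR, Benjamini-Hochberg), given as a difference of log2 changes. Genes beside Fli1 and antigen presentation genes were taken up because they moved alike in the 3 tissues.

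Between lung and liver, 1219 genes differed. Differences above 0 were Car3 11.25 (adjusted p = 0.0255), Tmem132e 7.13 (0.0399), Flrt3 6.85 (0.00251), Dnase1l3 6.27 (0.018), Erg 0.78 (0.0214) and Emcn 1.60 (0.00179). Those below 0 were Fat3 −11.59 (0.000259), Ppp1r14c −10.14 (9.65e-08), Lrrn3 −8.80 (0.000707) and Tnfrsf9 −8.20 (0.0316). For example, Dnase1l3 had 5052 ± 398 and 1145 ± 621 CPM in liver (adjusted p = 0.0555) and 0.0905 and 1.64 CPM in lung. Leaving out 1 library ended 5 of these calls, for Car3 with any of 6 libraries (adjusted p up to 0.348), Tmem132e 11 (0.106), Dnase1l3 2 (0.0587), Erg 3 (0.0517) and Tnfrsf9 9 (0.196). That for Flrt3 ended under limma voom (adjusted p = 0.0621).

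Between heart and liver, 1635 genes differed. Above 0 were Cd209b 14.26 (adjusted p = 0.0176), Hmga2 9.12 (0.00091), Ccn4 8.91 (0.00213), Fcrlb 8.90 (0.000177), Erg 0.84 (0.0226), Cldn5 1.03 (0.0393) and Vcam1 3.12 (0.0144). Below 0 were Cacna1h −8.63 (0.000387), Fat3 −8.50 (0.00201), Lrrn3 −8.35 (0.00495), Zbtb8b −7.55 (0.00178) and Kdr −1.23 (0.035). Calls ended here for Cd209b without any of 3 libraries (adjusted p up to 1), Cldn5 10 (0.125), Vcam1 3 (0.0846), Erg 4, all of heart (0.103), Lrrn3 1 (0.336) and Kdr 8 (0.137). The Ccn4 call ended under limma voom (adjusted p = 0.0516).

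Between heart and lung, 1257 genes differed. Above 0 were Igfbp2 10.22 (adjusted p = 0.0338), Hc 10.07 (0.00234), Cxcl15 9.47 (0.00032) and Lgi3 9.21 (8.28e-05). Of these, Hc, Cxcl15 and Lgi3 were lower in lung and higher in heart as lung epithelial markers were, for Cxcl15 89.2 to 11.4 CPM in lung and 0.0725 to 6.78 CPM in heart. Below 0 were Cyp1a1 −9.09 (0.00402), Adam23 −5.72 (0.00182), Abcb4 −5.38 (0.0119), Cdh23 −5.20 (0.00032), Kdr −1.43 (0.0223) and Emcn −1.77 (0.00267). Calls ended for Igfbp2 without any of 8 libraries (adjusted p up to 0.131), Abcb4 1 (0.0679) and Kdr 3 (0.112), and for Cyp1a1 under limma voom (adjusted p = 0.164). Of the 24 differences named by size over the 3 comparisons, in which Fat3 and Lrrn3 recur, 7 had 3 counts or fewer in a group. These were for Tmem132e, Cd209b, Hmga2, Fcrlb, Zbtb8b, Igfbp2 and Lgi3, so their fitted values depend on the prior count.

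Lung epithelial transcripts were higher in both knockout-labelled heart libraries, where the surfactant gene Sftpc had 46.0 and 81.7 CPM against 1.12 CPM in heart controls, 1075 CPM in lung controls and 118 CPM in knockout-labelled lung libraries. Lung endothelial cells or lung libraries mixed in are argued against, because 13 lung endothelial genes, held by heart controls at under 5% of the lung control level, gained a median of 0.0282% of that level (6 above both heart controls, the highest Plvap, 55.8 to 257 CPM against 2513 CPM in lung controls), while 7 genes of the epithelial list gave 5.30%. Of these 7 genes of the epithelial list, 6 lay above both heart controls. Hopx did not, with 3.39 CPM in heart controls and 3.38 CPM in knockout-labelled heart libraries. Against knockout-labelled lung libraries the endothelial and epithelial medians were 0.0249% and 30.6%. Further epithelial genes outside that list reached a median of 8.29% of the lung control level over 5 genes, 4 of them above both heart controls, so cells or RNA of the lung epithelium remain a candidate explanation. The CD45, CD31 and VE-cadherin gates do not speak against this, since lung controls sorted in the same way held 1075 CPM of Sftpc. Leukocyte and macrophage markers rose in the same heart libraries. Expression of these genes by the endothelium of knockout-labelled hearts was not tested.

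Of the genes beside Fli1, the 3 beyond its 3 prime end rose in all 9 tests (3 genes in 3 tissues), but they were taken up because they rose, so this does not test transcription running past the end of Fli1. A rise of the whole region by a like fold is argued against, because the highest log2 change of Arhgap32 and Ets1, the next genes on each side, was 0.15. Ets1 had 776 CPM or more in controls, where a gain like that of Kcnj1 (to 47.0 CPM in heart) would hardly show. For a gain of that size in CPM only Arhgap32 could tell. Read-through into Kcnj1, Gm39317 and Kcnj5 stays open, since the strand of the reads is not known, and of the 3 only Kcnj5 lies on the same strand as Fli1. Regulation of the 3 genes by Erg or Fli1 was not tested. Beside Erg, Kcnj15 fell in liver and lung (adjusted p = 0.000251 and 0.00323) and had 8.21 and 3.33 CPM in heart (0.0714), and Ets2, on the other side, had log2 0.64, 0.20 and 0.18 in liver, lung and heart (0.0125, 0.516 and 0.577).

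Of 22 antigen presentation genes, 20, 16 and 12 fell in liver, lung and heart and 0, 0 and 1 rose, with medians of −1.58, −1.08 and −0.84 (adjusted p = 0.268, 0.199 and 0.303 with an estimated correlation). Fewer leukocytes among the sorted cells are argued against as the whole cause, since pan-leukocyte medians were −0.95 in liver (lower quartile −1.43), −0.16 in lung and 1.82 in heart. Sex of the animals is argued against in liver and lung, where control and knockout-labelled groups held the same share of male libraries. A sex covariate could therefore hardly move those medians, and it adds no test there. In heart only a knockout-labelled library was male, and the median went from −0.84 to −0.88 with the covariate. Its sex effect was fitted over all tissues together, so it is a weak test for heart. At least 101% of each antigen presentation median was kept. Lower expression in endothelial cells of the knockout-labelled libraries stays open as a hypothesis. Lung epithelial markers also fell in the knockout-labelled lung libraries, and a part played by cells other than leukocytes was not tested. Multi-mapping among H2 genes was not tested either.

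Other splits of the libraries were counted for the comparisons of 3 against 3. There are 10 splits, too few for a share under 0.05. Every other split mixes libraries of both real groups, which widens the spread within groups. Low numbers of genes in other splits are thus partly built in and do not measure what chance gives. For genes changed in liver, 1 split (the real) reached 3814, and the highest other gave 0. In lung, 1 split reached 1663 and the highest other gave 1. Between lung and liver, 1 split reached 9238 in controls and 1 reached 7970 in knockout-labelled libraries, and the highest other gave 0 in each. Lists past the threshold in liver numbered 15, which 7 of the 10 splits reached (highest other 22), and in lung 12, which 5 reached (highest other 16). For the lung and liver interaction, 5 of 100 splits, the real included, reached 1219 (highest other 1683), a share not under 0.05. The 4 others were among 9 splits that kept liver as labelled and so hold the liver difference itself, and the highest with liver regrouped was 102.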

How the results depend on the processing

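Sex as a covariate, the heart count without lung-enriched genes and the correlations by description number were chosen after seeing the data. Single genes and differences were followed over all settings only if the rule for named genes took them up, mostly by size or small p. Of these, 305 of 422 gene calls and 15 of 32 called differences between tissues kept their direction and side of the threshold throughout. So did 1 of 47 list calls. No gene or difference that was followed reversed, and the other calls were not followed. Under DESeq2 the differences between tissues numbered 2022 (lung and liver), 2600 (heart and liver) and 2115 (heart and lung). Genes shared by the 3 tissues numbered 180 when a 2-fold change was asked for, which removes genes by construction. Liver lists numbered 7 in a separate fit, and lists with an estimated correlation 0, 1 and 0 in liver, lung and heart; the cause was not tested. With a replicate block, genes changed numbered 3412, 1367 and 3267, and with sex 3832, 1701 and 3827. Between tissues of 1 genotype, libraries with the same description number correlated at 0.019 to 0.143 in their deviations from group means (14 pairs, 4 over 0.1), others at −0.143 to 0.043. Of 12 liver and lung libraries, 11 correlated best with their own number, a hint from the data and not the design. With the title number as a block, differences between tissues numbered 1420 (lung and liver), 1450 (heart and liver) and 1210 (heart and lung). With the description number as a block they numbered 1739 (heart and liver) and 1463 (heart and lung). Without 1070 genes more than 10-fold higher in lung than in heart controls, heart had 3553 genes. Scaling moved the median of all genes by at most 0.032.

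Leaving out each library in turn gave 2622 to 3967 genes in liver, 917 to 2087 in lung and 1788 to 4243 in heart. The ranges for differences between tissues were 807 to 1269 (lung and liver), 711 to 1780 (heart and liver) and 467 to 1671 (heart and lung). Shared genes ranged from 274 to 484. Tissue comparisons of heart and lung controls gave 3467 to 6242, knockout-labelled heart and liver 4743 to 7473, and heart and lung 3482 to 6541. The lowest values came from leaving out a library of the comparison, and a group left with 1 library is assumed to vary like the others. The highest values for lung, for heart, for differences between heart and lung and for shared genes came without knockout-labelled liver library 3. That library enters the spread shared by all groups. Lists passing ranged from 11 to 17, 9 to 15 and 20 to 22. Directions turned for proliferation in liver (adjusted p = 0.962, range 0.0392 to 0.998, 0.0435 without control 2), immediate early genes in liver (0.0304, range 5.37e-07 to 0.998, 0.998 without knockout-labelled 3) and oxidative phosphorylation in heart (0.64, range 0.000584 to 0.835, 0.0309 without knockout-labelled 2), and the cause was not tested.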

Other observations

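Signalling and blood-lineage genes outside the accounts above, chosen after their values were seen, also changed. Ednrb, an endothelin receptor gene, rose in liver from 20.3 ± 8.58 to 669 ± 45.1 CPM (log2 5.05, adjusted p = 8.82e-06), and the ectonucleotidase gene Nt5e from 9.37 to 313 ± 186 CPM (adjusted p = 3.06e-06). Bmp6, an iron-regulating ligand of liver endothelium, fell from 391 ± 42.7 to 104 ± 25.03 CPM, and Gas6, a ligand of TAM receptors, from 815 ± 126 to 71.5 ± 33.1 CPM (adjusted p = 3.12e-05 and 5.68e-06). The platelet chemokine gene Pf4 rose in liver from 3.74 to 50.8 ± 8.23 CPM and in heart from 2.90 to 27.0 ± 8.89 CPM (adjusted p = 5.15e-05 and 0.00109). In lung, Acvrl1, a BMP receptor gene mutated in hereditary telangiectasia, fell from 3054 ± 335 to 1389 ± 154 CPM (adjusted p = 0.000253).

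A hypothesis was that genes restricted to the endothelium of 1 tissue fall in that tissue in particular. Genes at least 8-fold higher in 1 tissue than in both others, at 10 CPM or more, were chosen in control replicate 1 alone, other-cell lists excluded, and the change was measured against the remaining controls. In their own tissue, 215 liver-restricted genes had a median log2 change of −0.89 (79.1% lower) and 220 lung-restricted genes −0.56 (73.6% lower). Matched random sets had medians of −0.05 and −0.01, and 0% of 10000 sets per tissue were as low. These sets draw genes as if independent and do not measure the spread between libraries. Liver-restricted genes had a median of 0.14 in lung, and lung-restricted genes 0.11 in liver. For 128 heart-restricted genes the median in heart was −0.93, but with 1 control library left no spread could be had, so this decides nothing. The liver and lung values show a larger fall of these genes in their own tissue than of matched genes. Whether that fall is particular to the tissue is not decided. The genes were chosen to be low in the other tissues and had less room to fall there. Other cells of a tissue that the lists do not hold could add to the fall.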
